A study of Mus musculus with 6 samples.

How the data were processed

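RNA was profiled by bulk sequencing in 6 libraries of mouse Th17 cells, the CD4 T helper cells defined by production of interleukin 17. Per the labels, Sirt2 had been knocked out with CRISPR/Cas9 in 3 libraries (Sirt2 KO, replicates 1 to 3) and 3 were controls (Sirt2 WT, replicates 1 to 3). Per the labels' protocols, the cells were stimulated for 72 hours with antibodies against CD3 at 0.5 μg/mL and CD28 at 1 μg/mL, which engage the T cell receptor and its costimulator, and total RNA was taken with a silica column kit. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether replicates came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

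The authors deposited a gene table of 24182 genes and a transcript table of 73900 transcripts, both in FPKM, fragments per kilobase of transcript scaled to the library total, with a column per library per the file headers. The submitters' processing notes name cutadapt, FastQC, HISAT2, StringTie, DESeq2 and edgeR, without versions, roles or order. Those notes name the build mm9, but 73240 of the 73430 transcript IDs found in the GENCODE annotation of GRCm38 had the same chromosome, start, end and strand there, so coordinates are given as GRCm38. The deposited fold column, a ratio, equalled the mean FPKM of KO over that of WT within 0.1 percent for 24087 of the genes, with means raised to at least 0.0001 FPKM. The deposited log2 column is its logarithm, per the file headers. The deposited p-value and q-value columns give a test of KO against WT per feature, and which tool made them is not given in the sources used here. The authors also deposited an enrichment table, with a p-value and other numbers (genes of each term among significant and among annotated genes) for 835 Gene Ontology terms.

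Read depth is unknown because the tables hold no counts. At most 5 percent of the low values of single-exon transcripts fell on a whole multiple of a common step within 0.02 steps, so whole reads were not recovered. No counting interval or detection floor is given, and a value of 0 is described only as listed at 0. FPKM per library is relative to that library's own total, so a shift in a few abundant genes moves the others.

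Because the values are FPKM, a count test was not used. Genes were kept at 1 FPKM or more in at least 3 of the 6 libraries, which left 10873 genes and, by the same rule, 19184 transcripts. KO was compared with WT on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean trend in the variance and Benjamini-Hochberg adjustment, and adjusted p under 0.05 was called. "Rose" and "fell" are used of features called in this way. Fold changes on the log2(FPKM + 1) scale understate the change of low genes. Sirt2, Il17a and Il2 also had an exact two-sided permutation test on the 6 values.

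The 28 gene lists were fixed before the data were examined. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. fry was run beside them. Named genes follow a rule also fixed then. It takes Sirt2, Il17a and Il2, and the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 FPKM and groups that do not overlap, leaving out unnamed loci. With fewer than 3 such genes in a direction, those of smallest unadjusted p are added up to 6 and said not to pass. Up to 4 members of each list with the smallest p and up to 4 Sirt2 transcripts of highest mean complete it.

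The alternatives fixed beforehand were scaling to a common median, no filter, a filter at 5 FPKM, a pseudocount of 0.1, no mean trend, adjusted p under 0.01, an absolute log2 fold change of 1 or more, the replicate number as a block, and leaving out each library in turn with the same filter over the 5 libraries left. Removal of gene length and GC content trends was added after the data were seen, with lengths and GC content from the reference transcripts for 99.7 percent of the tested genes.

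The fits were tested on simulated data made from the real means and spreads with 200 changed features. Over 10748 simulated genes of the gene comparison, 62.0 percent of genes changed by 0.5 on the log2 scale were called, 81.6 percent of those changed by 1 and 98.0 percent of those changed by 2. Over 18346 simulated transcripts of the transcript comparison these shares were 10.4, 21.3 and 66.0 percent. In a simulation of the list comparison over 10873 genes, both raised lists were called, as was 1 of 20 lists with no raised gene. Noise was drawn independently for each gene and library in these simulations, so list members were uncorrelated and no library deviated as a whole. In the real data the estimated correlation was 0.60 for ribosomal proteins and 0.63 for oxidative phosphorylation, so the simulated shares need not hold there. Figures were drawn with matplotlib 3.10.9.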

Results

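The study measured gene expression in activated mouse Th17 cells labelled as Sirt2 KO or as WT controls, with 3 libraries per genotype. Sirt2 encodes a NAD-dependent deacetylase. The sum of gene FPKM was 303772 to 321734 per library, and 10642 to 10958 genes reached 1 FPKM. Read depth is unknown from these tables. Over the tested genes, log2(FPKM + 1) of KO replicate 3 correlated at 0.981 and 0.979 with KO replicates 1 and 2, and at 0.990 with each of the 3 WT libraries, while KO replicates 1 and 2 correlated at 0.992 with each other. These are correlations across genes, which are not independent replicates.

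The first comparison asked how the targeted gene and both cytokines named in the study's title, Il17a and Il2, differed between genotypes. Sirt2 (ENSMUSG00000015149, GRCm38 chromosome 7, 28766735 to 28788661, plus strand) fell to 11.9 ± 1.41 FPKM (SD, n = 3) in KO from 20.8 ± 0.999 FPKM in WT, a ratio of means of 0.572. Its values were 11.2, 13.5 and 10.9 FPKM in KO replicates 1 to 3 and 20.7, 19.9 and 21.9 FPKM in WT replicates 1 to 3, so that KO was lower in each library in accord with the labels. The log2 fold change was -0.76 (SE 0.0920, limma adjusted p = 0.0429), and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. The size held in the 12 alternatives for which it was recorded (-0.85 to -0.71), but the call held in 4 of them, with limma adjusted p from 0.00783 to 0.376. The filter at 5 FPKM, not among these 12, also ended the call. Among the alternatives that ended it were the fits without KO replicate 1 (0.376), WT replicate 1 (0.218), WT replicate 2 (0.235) or WT replicate 3 (0.338), and those after median scaling (0.0772), without the filter (0.131) and without the mean trend (0.0621).

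Il17a, the signature Th17 cytokine (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496), was at 19.8 ± 5.999 FPKM in KO and 22.9 ± 1.54 FPKM in WT. Its log2 fold change of -0.23 (95% interval -0.65 to 0.19, limma adjusted p = 0.870, exact permutation p = 0.4, two-sided) did not exceed the spread between replicates. Il2, the T cell growth factor (ENSMUSG00000027720, chromosome 3, 37120523 to 37125959), was at 46.7, 31.0 and 14.6 FPKM in KO replicates 1 to 3 and 17.8 to 20.2 FPKM in WT. Its log2 fold change was 0.54 (95% interval -0.28 to 1.36, limma adjusted p = 0.865, exact permutation p = 0.4). Without KO replicate 3, whose value lay below every WT library, the Il2 difference was 0.98 and passed the threshold (limma adjusted p = 0.0177). Over the 12 alternatives recorded for Il2 the limma adjusted p ran from 0.0177 to 0.9999.

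**Figure D1:**
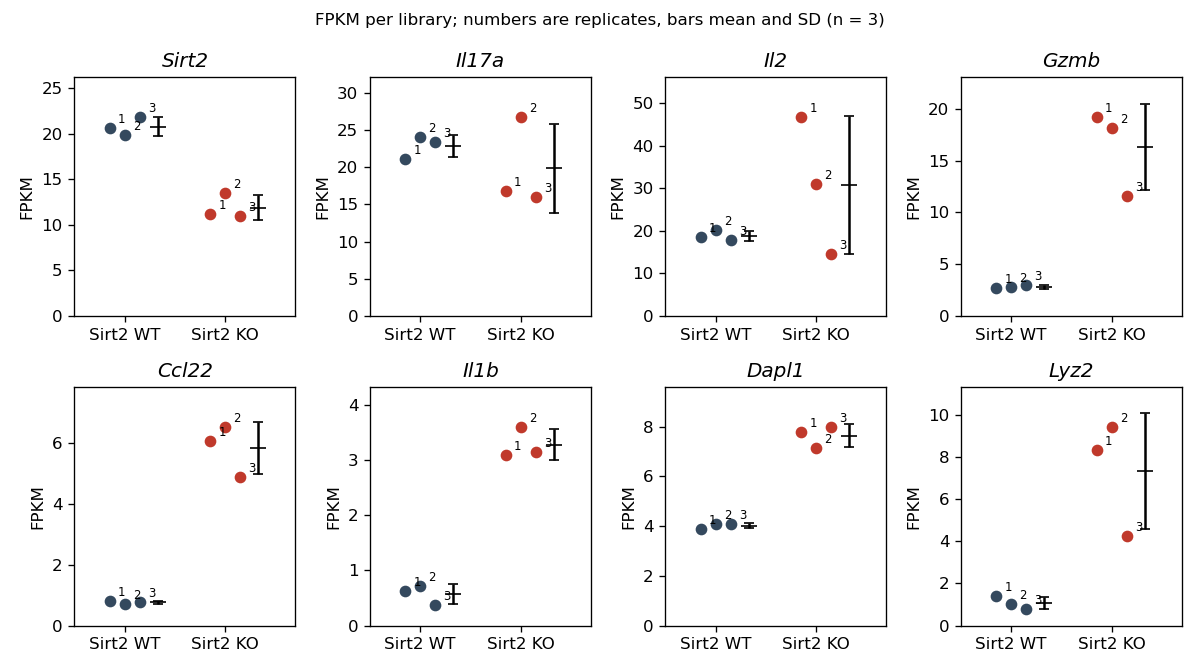
FPKM (linear axis from 0) of 8 genes in the 3 Sirt2 WT and 3 Sirt2 KO libraries, with points numbered by replicate and bars for the mean and SD (n = 3). Sirt2 was lower and Gzmb, Ccl22, Il1b, Dapl1 and Lyz2 were higher in all 3 KO libraries, while the groups overlapped for Il17a and Il2, with Il2 at 46.7 FPKM in KO replicate 1 and 14.6 FPKM in KO replicate 3.

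The second comparison asked which genes of the whole table differed. Gzmb, the serine protease of cytotoxic granules (chromosome 14, 56258838 to 56262260), rose to 16.3 ± 4.13 FPKM from 2.80 ± 0.156 FPKM in WT, a log2 fold change of 2.16 (SE 0.173, limma adjusted p = 0.00675), and its paralog Gzmc rose to 1.87 ± 0.361 from 0.207 ± 0.151 FPKM (limma adjusted p = 0.0375). Ccl22, a chemokine ligand of CCR4 (chromosome 8, 94745590 to 94751699), rose to 5.83 ± 0.847 from 0.764 ± 0.0481 FPKM, a log2 fold change of 1.95 (SE 0.114, limma adjusted p = 0.00278). Il1b, the inflammatory cytokine interleukin 1 beta, rose to 3.29 ± 0.285 from 0.571 ± 0.185 FPKM (log2 fold change 1.45, limma adjusted p = 0.00675). Beside these rises, 20 of 46 myeloid, B cell and cytotoxic markers, Gzmb and Gzmc among them, were higher in all KO than all WT libraries. Of these markers 0 were lower, where chance gives 5 percent in each direction. Their lists were fixed beforehand, but they were pooled after the values were seen. In the erythroid and fibroblast list, left out of the pool, 1 of 15 was higher in all KO libraries. Gzmb and Gzmc are paralogs, and how reads shared between paralogs were counted is not given.

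In all, 12 of 10873 genes passed, 10 higher and 2 lower in KO, and 610 had an unadjusted p under 0.05. The other named rises were Cdk5rap1, a tRNA-modifying enzyme, at 9.20 ± 0.485 against 3.93 ± 0.102 FPKM, Dapl1 at 7.65 ± 0.448 against 4.02 ± 0.116 FPKM, and Traj27, a joining segment of the T cell receptor alpha locus. Traj27 was at 6.04 to 7.02 FPKM in KO and at 1.03 FPKM in WT replicate 1, and was listed at 0 in WT replicates 2 and 3. This segment is short (chromosome 14, 54192303 to 54192361), so few fragments may lie behind these values, which cannot be told without counts. Its deposited q was 0.151, and it was the only called gene whose deposited q was not under 0.05. The remaining rises were the unnamed loci Gm49980, Gm42031 and Gm46620. Syce1, a component of the synaptonemal complex, fell to 0.113 ± 0.0885 from 2.38 ± 0.463 FPKM (log2 fold change -1.59, limma adjusted p = 0.00675), and the second fall was Sirt2. Of the lower genes with the next smallest p, which did not pass, Rpl30-ps9 had a log2 fold change of -1.21 (adjusted p = 0.0591), Erdr1 of -0.62, Mir6974 of -0.58 and Evi2b of -1.52. Rpl30-ps9 is a processed pseudogene of a ribosomal protein gene and Mir6974 a microRNA gene, so reads of other genes can enter their values. Evi2b overlaps Evi2, which went the other way. Evi2 was at 2.63, 2.77 and 6.63 FPKM in KO and 0.0764 to 0.232 FPKM in WT (limma adjusted p = 0.0659).

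This count rested on single libraries. Without KO replicate 3 there were 1088 calls, 429 higher and 659 lower, and without KO replicate 1 there were 0 by limma, with 346 genes at an unadjusted p under 0.05. There were 6 calls without KO replicate 2 and 6 without WT replicate 1, 1 without WT replicate 2 and 4 without WT replicate 3. In each of these fits every one of the 12 genes that was still tested kept its sign. Of the 12, 8 were tested without KO replicate 1, 2 or 3 and 11 without any one WT library. Ccl22, Il1b, Gzmc and Gm42031 were under 1 FPKM in every WT library and reached the filter only through all KO libraries. Syce1, under 1 FPKM in every KO library, reached it only through all WT libraries. Part of the loss of calls therefore came from the filter. With a filter at 5 FPKM 5 genes were called, and at adjusted p under 0.01 there were 7. Without the filter only 3 of the 12 kept their call (Ccl22, Cdk5rap1 and Gm49980), while limma adjusted p was 0.0721 for Gzmb, Il1b and Syce1, 0.131 for Gzmc and 0.131 for Sirt2.

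The third comparison asked whether gene groups fixed beforehand differed. Among effector programmes, the cytotoxic and NK cell list had the largest median. Of its 5 measured members 2 rose (Gzmb and Gzmc) and none fell, or 3 adjusted over the list alone, with a median log2 fold change of 0.93 (camera adjusted p = 3.3e-08, and adjusted p = 0.0898 with an estimated correlation). The third was Nkg7, a granule membrane protein, at 2.37 ± 0.445 FPKM in KO and 0.770 ± 0.171 FPKM in WT (adjusted p over all genes = 0.0829), whereas Klrd1 and Cd8b1 overlapped between groups. Gzmc and Nkg7 were under 1 FPKM in every WT library and reached the filter through the KO libraries, so the filter itself favoured members higher in KO. Without it 13 members were measured, of which 0 passed over all genes and 8 rose adjusted over the list alone. The list passed in that fit (camera adjusted p = 1.2e-13, and adjusted p = 0.0321 with an estimated correlation). Over its 10 alternatives the median ran from 0.32, without the filter, to 1.51, at a pseudocount of 0.1, and without KO replicate 1, 2 or 3 fewer than 5 members were measured and the list could not be tested. Markers of other cell types were measured beside it. The myeloid lysozyme gene Lyz2 was at 8.31, 9.44 and 4.24 FPKM in KO and 0.782 to 1.38 FPKM in WT (limma adjusted p = 0.0503), and passed adjusted over the list alone as 1 of 3 measured myeloid markers, while Cd68 and Ctss did not. The single measured B cell marker, Ighm, the immunoglobulin mu heavy chain, was at 22.9 ± 2.15 against 18.5 ± 0.158 FPKM (limma adjusted p = 0.724). With 1 measured member, adjustment over the list alone leaves its unadjusted p (limma, 0.00692) as it was. Of the erythroid and fibroblast list 2 members were measured, Thy1 and Pecam1, of which 0 passed, also adjusted over the list alone. T cells express Thy1 themselves (98.8 to 116 FPKM over all libraries), so it says nothing about other cells. Without the filter, 19 myeloid and 14 B cell markers were measured, and both lists were higher in KO (camera adjusted p = 2.1e-06 for each). With an estimated correlation the camera adjusted p was 0.126 and 0.236, in that order. Of their members 0 passed over all genes, and 5 and 4 rose adjusted over the list alone. The erythroid and fibroblast list, with 15 measured, was not called (camera adjusted p = 0.908).

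The NF-kB target list (median 0.16, camera adjusted p = 1.03e-05) and the list of IL-2 and T cell activation genes (median 0.14, camera adjusted p = 1.3e-04) were higher in KO as sets. With an estimated correlation both lost the call, at adjusted p = 0.0898. None of their 18 measured members each passed on its own with all libraries, over all genes or adjusted over the list alone. Without KO replicate 3, 3 NF-kB targets rose and 0 fell (4 and 0 adjusted over the list alone), and 3 activation genes rose and 3 fell (8 and 3). Among NF-kB targets, Traf1, a TNF receptor adaptor, was at 10.4 ± 0.241 against 8.30 ± 0.603 FPKM and Icam1, an adhesion molecule, at 11.7 ± 0.388 against 10.04 ± 0.400 FPKM. Nfkbia, the NF-kB inhibitor, was at 84.9, 78.5 and 62.9 FPKM in KO and 56.9 to 64.6 FPKM in WT. In the activation list, Cd44 was at 24.9 ± 1.34 against 21.7 ± 0.834 FPKM, and Il3 and Tnfrsf4 were also higher in all KO than all WT libraries.

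The Th1 list was higher in KO as a set (median 0.09, camera adjusted p = 0.0122, adjusted p = 0.262 with an estimated correlation), with 0 of 11 members passing over all genes and 1, the chemokine gene Ccl3, adjusted over the list alone. Tbx21, which encodes the Th1 transcription factor T-bet, was at 3.11 ± 1.16 against 1.57 ± 0.0749 FPKM (limma adjusted p = 0.806). The Th1 call by camera was lost without KO replicate 1 (adjusted p = 0.0551), 2 (0.134) or 3 (0.331), and over its alternatives the adjusted p ran from 0.00146 to 0.331. In these fits its median was 0.0465, -0.0226 and 0.00354, in that order, so that neither its size nor the sign of its median was kept. Its mean stayed above 0 (0.0752, 0.0823 and 0.0526), and camera's direction stayed higher in KO. Ccl3, under 1 FPKM in every WT library, missed the filter in these fits, which left 10 members.

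The Th17 list itself did not differ (median -0.24, camera adjusted p = 0.193, adjusted p = 0.829 with an estimated correlation), and 0 of 18 members passed, also adjusted over the list alone. Its members pointed both ways. Maf, a transcription factor, was at 10.3 ± 2.14 against 14.7 ± 0.946 FPKM, and Ahr, the aryl hydrocarbon receptor, at 24.1 ± 4.92 against 30.7 ± 1.73 FPKM, whereas Il22 was at 7.48 ± 1.62 against 5.20 ± 0.689 FPKM. The list mean over the WT mean was -0.28 and -0.20 (log2) in KO replicates 1 and 2 and 0.09 in KO replicate 3. Without KO replicate 3 the list was lower in KO (median -0.37, camera adjusted p = 0.00810, and adjusted p = 0.483 with an estimated correlation), and over its alternatives the adjusted p ran from 0.00810 to 0.829. In that fit 8 of 17 measured members fell and 1 rose over all genes, or 10 and 2 adjusted over the list alone. The interferon response list had 0 of 11 members passing with all libraries, also adjusted over the list alone. Without KO replicate 3, 2 of 11 fell over all genes and 6 adjusted over the list alone, and the list passed as lower (camera adjusted p = 0.0464, and adjusted p = 0.483 with an estimated correlation). Over its alternatives the interferon adjusted p ran from 0.0464 to 0.906, with 0.264 for all libraries.

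**Figure D2:**
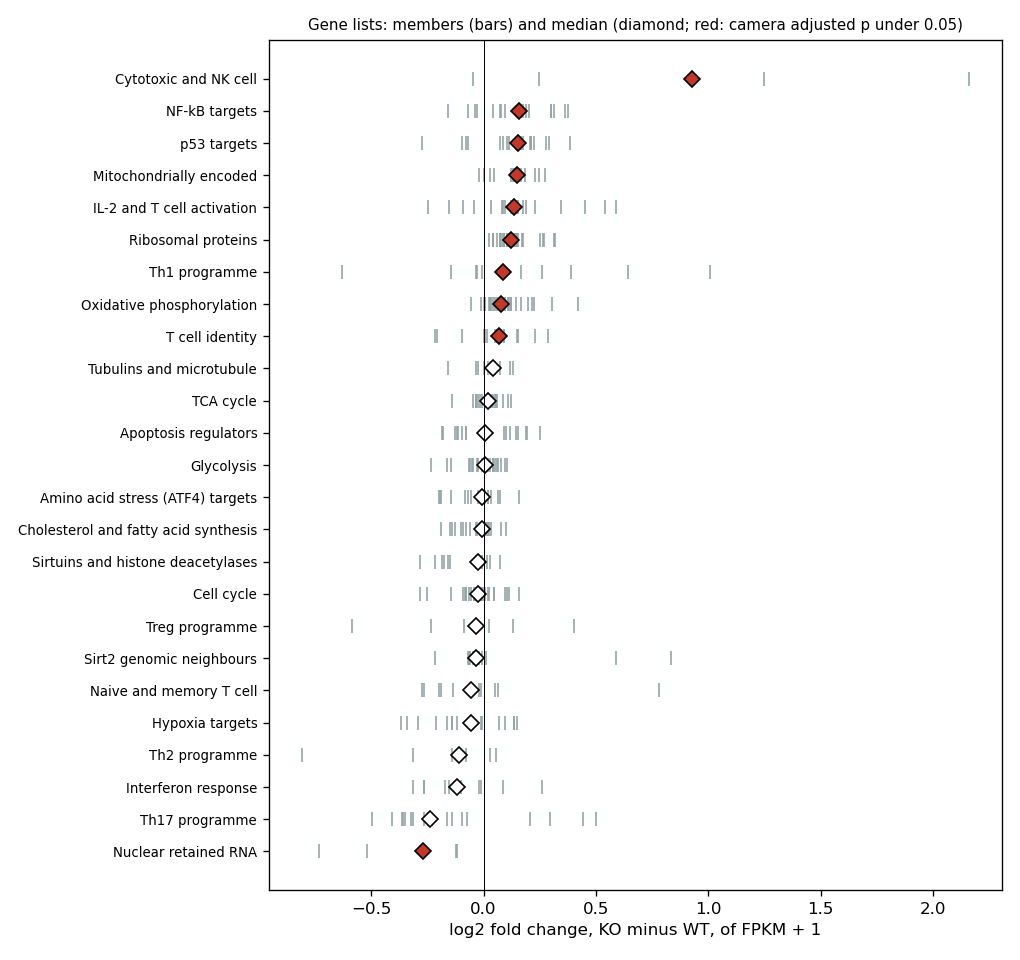
Log2 fold change of FPKM + 1 (KO minus WT) for the measured members (grey bars) and the median (diamonds) of the 25 lists tested, red where the camera adjusted p was under 0.05. The cytotoxic and NK cell median of 0.93, which was 0.32 without the filter, stands apart from the other 24, and the nuclear retained RNA median of -0.27 is the only called one below 0.

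Of the remaining called lists, ribosomal protein genes (29 measured, median 0.12, camera adjusted p = 3.39e-09) were higher in KO as a set. So were oxidative phosphorylation genes (29 measured, median 0.08, camera adjusted p = 1.64e-05) and mitochondrially encoded genes (15 measured, median 0.15, camera adjusted p = 1.03e-05). The same held for p53 targets (18 measured, median 0.15, camera adjusted p = 0.00123) and T cell identity genes (17 measured, median 0.07, camera adjusted p = 0.00440). Nuclear retained RNAs (5 measured, median -0.27, camera adjusted p = 0.00218) were lower. In these 6 lists 0 members passed with all libraries, also adjusted over the list alone. Without KO replicate 3, 12 of 29 ribosomal protein and 10 of 29 oxidative phosphorylation genes rose and 0 fell (14 and 12 rose adjusted over the list alone), and 8 of 18 p53 targets rose and 1 fell (10 and 1). In that fit 1 of 15 mitochondrially encoded genes rose (5), 2 of 5 nuclear retained RNAs fell (4), and of 17 T cell identity genes 1 rose and 1 fell (1 and 3). With an estimated correlation the adjusted p was 0.443 for ribosomal proteins, mitochondrially encoded genes and p53 targets, 0.645 for oxidative phosphorylation, and 0.410 for T cell identity and nuclear retained RNAs, so that no list kept its call. KO replicate 3 did not share several of these shifts. The mean of ribosomal protein genes over the WT mean was 0.20 and 0.24 (log2) in KO replicates 1 and 2 and -0.03 in KO replicate 3, and that of p53 targets 0.23, 0.17 and -0.04. For mitochondrially encoded genes it was 0.06, 0.27 and 0.06 in KO replicates 1 to 3 and 0.08 in WT replicate 1, and without KO replicate 2 their median was 0.0586 (camera adjusted p = 0.00834, and adjusted p = 0.764 with an estimated correlation). Across 10844 tested genes, which are not independent replicates, the Spearman correlation of gene length with the difference from WT was -0.33, -0.46 and 0.23 in KO replicates 1 to 3. Malat1, a nuclear noncoding RNA, was at 2.44, 1.69 and 3.32 FPKM in KO and 3.47 to 4.51 FPKM in WT. The oxidative phosphorylation call by camera was lost without KO replicate 2 (adjusted p = 0.0612), the p53 call without KO replicate 1 (0.0783), and the T cell identity call without KO replicate 2 (0.112) and with length and GC trends removed (0.0937). Over the alternatives their camera adjusted p ran from 4.68e-09 to 0.645, 4.54e-05 to 0.443 and 0.00137 to 0.410, in that order.

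**Figure D3:**
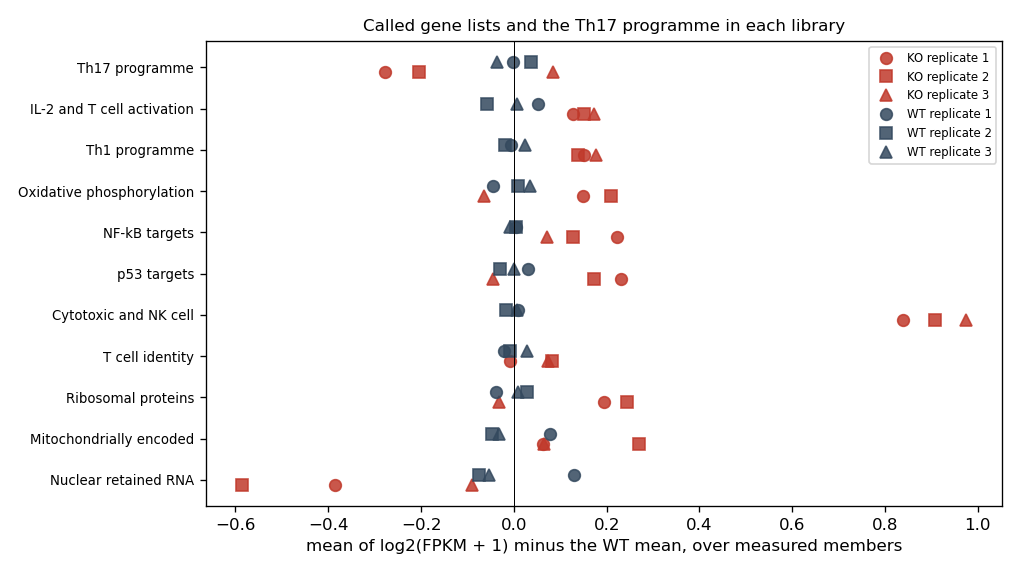
Mean over each list's measured members of log2(FPKM + 1) minus the WT mean, for the 10 called lists and the Th17 programme, with 3 KO libraries in red and 3 WT libraries in blue. In KO replicate 3 (red triangles) ribosomal proteins sit at -0.03 and p53 targets at -0.04, near the WT libraries, whereas the cytotoxic and NK cell list sits at 0.97, beside 0.84 and 0.91 in the other KO libraries.

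The other lists were not called with all libraries. Camera adjusted p was 0.258 for the Th2 programme, 0.980 for the Treg programme, 0.980 for naive and memory T cell genes, 0.282 for glycolysis, 0.225 for the TCA cycle, 0.801 for cholesterol and fatty acid synthesis, 0.978 for amino acid stress targets, 0.801 for the cell cycle, 0.166 for apoptosis regulators, 0.989 for hypoxia targets, 0.225 for sirtuins and histone deacetylases and 0.244 for tubulins. Over all genes, Dapl1 in the naive and memory list was the only passing member, and it also passed adjusted over the list alone. Sirt2 itself is in none of these lists. Il9 was at 45.4, 100.1 and 75.1 FPKM in KO and 114 to 129 FPKM in WT (limma adjusted p = 0.806), and Sirt6, another sirtuin, at 6.16 ± 0.820 against 7.67 ± 0.375 FPKM. For hypoxia targets and naive and memory genes, the median (-0.06 for both) and the camera direction (higher) differed in sign. Some of these lists passed when a library was left out. By camera, hypoxia targets were lower without KO replicate 3 (adjusted p = 0.00319) and tubulins higher without it (0.0188), glycolysis higher without KO replicate 1 (0.0225) and apoptosis regulators higher without KO replicate 2 (0.00981). In the same fits all 4 calls were lost, at adjusted p = 0.437, 0.560, 0.796 and 0.377 with an estimated correlation, in that order. Over the alternatives the highest adjusted p of these lists was 0.996, 0.829, 0.829 and 0.673, in that order. The mean of hypoxia targets over the WT mean was -0.26 and -0.27 (log2) in KO replicates 1 and 2 and 0.30 in KO replicate 3.

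Genes next to Sirt2 on chromosome 7 formed a list of 13 measured members (median -0.04, mean 0.07, camera direction higher, adjusted p = 0.504), so that median and test differed in sign. Over all genes 0 passed, but Fbxo17, an F-box gene (28716804 to 28738144), and Lgals7, a galectin gene (28863853 to 28866284), passed as higher adjusted over the list alone. Fbxo17 was at 3.99 ± 0.7005 against 1.80 ± 0.443 FPKM and Lgals7 at 3.21 ± 0.339 against 1.80 ± 0.309 FPKM.

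**Figure D4:**
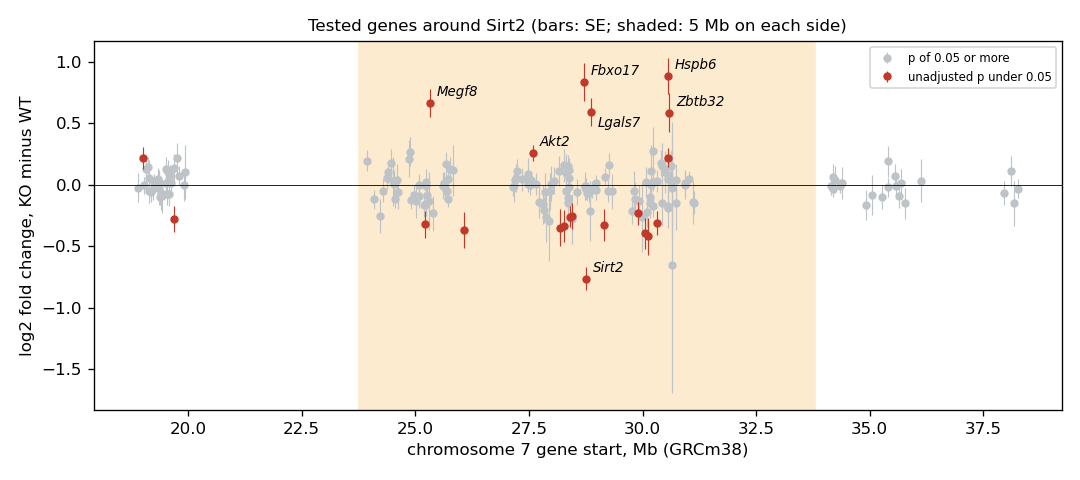
Log2 fold change (KO minus WT) with SE for each tested gene by its start on chromosome 7 (Mb, GRCm38), red where the unadjusted p was under 0.05, with 5 Mb on each side of Sirt2, a width chosen after the values were seen, shaded. In the shaded window 18 of 135 genes other than Sirt2 are red.

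The fourth comparison used the transcript table. Of 19184 transcripts 8 passed, 3 higher and 5 lower in KO, and 1068 had an unadjusted p under 0.05. A transcript of the ribosomal protein gene Rpl10a (ENSMUST00000232867) was listed at 0 in all 3 KO libraries and at 219.5 to 238 FPKM in WT, and one of the lactate dehydrogenase gene Ldha (ENSMUST00000209548) was listed at 0 in KO and at 505 to 726 FPKM in WT. A transcript of Trim27, a ubiquitin ligase gene (ENSMUST00000223065), was at 27.9 to 32.3 FPKM in KO and listed at 0 in WT, and another Trim27 transcript fell to 11.6 ± 0.397 from 25.8 ± 1.00 FPKM. For Mvd, a mevalonate pathway gene, one transcript fell to 0.134 ± 0.101 from 20.6 ± 1.69 FPKM while another rose to 38.0 ± 2.33 from 16.8 ± 0.803 FPKM. The other calls were Bak1 (lower) and Ccl22 (higher). The gene totals of Rpl10a, Ldha, Trim27, Mvd and Bak1 had log2 fold changes of -0.01, 0.10, 0.02, -0.01 and 0.09, each within 2 SE. FPKM of isoforms that overlap each other depend on how the authors' tool shared reads between them.

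The most abundant Sirt2 transcript (ENSMUST00000072965, 16 exons, 28766767 to 28788660) was at 17.7 ± 5.34 FPKM in KO and 35.4 ± 6.63 FPKM in WT (log2 fold change -0.99, limma adjusted p = 0.703), with each KO library below each WT library. ENSMUST00000122915 was at 13.5 ± 4.99 against 19.3 ± 2.65 FPKM and overlapped between groups. ENSMUST00000155327 had means of 0.342 FPKM in KO and 1.15 FPKM in WT, with each KO library below each WT library. ENSMUST00000170068 had means of 0.778 FPKM in KO and 0.603 FPKM in WT and overlapped between groups. Both were below the filter. The count of called transcripts was 4 without the filter, 4 without KO replicate 2, 5 without KO replicate 3, and 1 without WT replicate 1, 2 or 3.

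The authors' deposited table marked 71 genes, 57 higher and 14 lower in KO, and gave 102 genes a q-value under 0.05. Of the 12 genes called here 9 were marked there and 11 had a deposited q under 0.05. Of the 71 marked genes, 49 were below the filter of 1 FPKM in 3 libraries, and 4 were listed at 0 in at least 5 of the 6 libraries. The 22 that were tested all had the same sign here. The authors' deposited table gave Sirt2 a log2 fold of -0.81 and a q of 4.07e-08 without a mark. Dapl1, with a deposited log2 fold of 0.93 and a q of 7.9e-04, had no mark either. Among the marked genes the smallest absolute deposited log2 fold was 1.13 (Gm49980). Of 835 Gene Ontology terms in the authors' deposited table, 413 had p under 0.05 and 144 an adjusted p under 0.05 when adjusted here. The lowest p in the authors' deposited table, 7.95e-08, belonged to neutrophil chemotaxis, with 6 of 60 significant against 56 of 15267 annotated genes. The background was these 15267 annotated genes, and how they were chosen is not given in the sources used here.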

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

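The removal of length and GC trends was chosen after the data were seen, and all other alternatives were fixed before. Same-numbered libraries did not deviate together (correlations of deviations 0.00668, -0.0170 and -0.0756), so the numbers were not taken to pair the samples. With the replicate number as a block, 13 genes passed, of which 10 were among the 12, with 12 higher and 1 lower. Transcripts numbered 3 (1 higher, 2 lower). Sirt2 stayed at -0.76 but lost its call (limma adjusted p = 0.135), as did Dapl1 (0.0871). Each KO library correlated best with a WT library of another number. Median scaling gave 13 genes (12 higher, 1 lower) and moved the median of all genes from -0.03 to 0.01, with Sirt2 at -0.72. Without the filter 8 genes passed (8 higher, 0 lower, 3 of them among the 12) and 4 transcripts (1 higher, 3 lower), Sirt2 at -0.76; more genes were tested. A filter at 5 FPKM gave 5 genes (5 higher, 0 lower). Of the 12, 6 were no longer tested, and Sirt2 was tested but not called. No mean trend gave 12 (11 higher, 1 lower), with Sirt2 at -0.76. At adjusted p under 0.01 there were 7 genes (6 higher, 1 lower) and 4 transcripts (1 higher, 3 lower), and with an absolute log2 fold change of 1 or more, 10 genes (9 higher, 1 lower). With an estimated correlation 0 lists passed by camera with the main filter, while 4 had an unadjusted p under 0.05. Without the filter the cytotoxic and NK cell list passed (camera adjusted p = 0.0321 with an estimated correlation). With the main filter the unadjusted fry p was 2.0e-04 for that list, 0.00110 for the Th1 list and 0.0137 for NF-kB targets. For the other called lists it ran from 0.0591 (nuclear retained RNAs) to 0.370 (oxidative phosphorylation). Removing length and GC trends gave 16 genes, the 12 among them. Apart from what is said here the cause was not tested.

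Leaving out each library in turn gave 0 to 1088 genes (0 to 429 higher, 0 to 659 lower), 1 to 6 transcripts (0 to 1 higher, 0 to 6 lower) and 7 to 12 lists. Log2 fold changes ran from -0.85 to -0.71 for Sirt2, -0.46 to -0.10 for Il17a and 0.17 to 0.98 for Il2. These gene directions turned in 1 such fit each, none called: Ccr4 (-0.173 to 0.0134), Tuba1b (-0.0224 to 0.187), Pecam1 (-0.257 to 0.0507), Pkm (-0.0154 to 0.138), Klrd1 (-0.0342 to 0.417) and Ctss (-0.0152 to 0.108).

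Camera's direction turned only for lists not called with all libraries, but the median of the called Th1 list was -0.0226 without KO replicate 2. The list medians were then 0.0319 (cholesterol synthesis), 0.0341 (amino acid stress), 0.0175 (cell cycle) and -0.0279 (hypoxia) after median scaling; -0.0108 (Th2), -0.0403 (Treg) and -0.0493 (hypoxia) without the filter; -0.0554 (naive and memory) and -0.0558 (hypoxia) with the block; -0.108 (hypoxia) at a pseudocount of 0.1; -0.0558 (hypoxia) without the mean trend; and 0.00816 (cholesterol synthesis) and -0.0392 (Sirt2 neighbours) with length and GC trends removed. With a library left out, medians of lists that turned ran from -0.0831 to 0.0699 (Treg), -0.0379 to -0.00142 (amino acid stress), -0.0350 to 0.00393 (cholesterol synthesis), -0.303 to -0.0500 (interferon), -0.0301 to 0.0860 (tubulins), -0.0552 to 0.00949 (Sirt2 neighbours), -0.158 to -0.0394 (naive and memory), -0.0616 to 0.0713 (glycolysis), -0.0537 to 0.0140 (cell cycle) and -0.219 to 0.0494 (hypoxia, with the turn called without KO replicate 3). The depth is unknown, so what it limits cannot be given.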

Other observations

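The tests here were chosen after the data were seen, those of length and GC content before their own results were. Many myeloid, B cell and cytotoxic markers, most of them below the filter, were higher in KO. Of the 46 in the table above 0, of which 9 reached the filter, all KO libraries lay above all WT libraries for 20 and below for 0, where chance gives 5 percent in each direction. Among them, Cd14, the endotoxin coreceptor, was at 0.881, 1.09 and 1.49 FPKM in KO and 0.0245 to 0.121 FPKM in WT, and Fcer1g at 0.563 to 0.858 against 0.0749 to 0.230 FPKM. Some genes marked in the deposited table were picked after their values were seen, and because they were higher in KO, so they add no evidence. Il1a was at 2.33 to 3.76 FPKM in KO and 0.768 to 1.29 FPKM in WT. Trdc, the constant gene of the T cell receptor delta chain, was at 0.823 to 1.24 FPKM in KO and 0.228 to 0.5005 FPKM in WT, and Ifng, the Th1 cytokine and a member of the Th1 list, at 0.547 to 1.08 against 0.102 to 0.166 FPKM. Of erythroid and fibroblast markers, 1 of 15 was higher in all KO libraries, with Thy1, which T cells express, among the 15. Ctss, the most abundant myeloid list gene, was at 26.3 to 31.4 FPKM in KO and 26.6 to 28.4 FPKM in WT, and Tyrobp, abundant in myeloid cells, at 0.627 FPKM at most in KO, overlapping WT.

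A candidate source of these transcripts is a small share of other cell types in the KO cultures, for which the labels name no sort or gate. Random gene sets of the same abundance held 2 such genes in the median and 5 at the 95th percentile, and the share of 10000 sets with as many as 20 was 1e-04, the smallest they can give. This count restates the pattern and does not separate other cells from expression by the Th17 cells. The genes of each random set were drawn independently, whereas markers of a cell type can vary together between libraries. Without the filter the estimated correlation was 0.226 for the B cell list, 0.0765 for the myeloid list and -0.0356 for the cytotoxic list. The share is therefore not a p-value. Of the 11111 genes in that abundance range under 1 FPKM, 4.10 percent lay higher in all KO libraries and 4.64 percent lower. Low genes as a whole were therefore not shifted upward in KO. FPKM is scaled to each library's total, so these shares cannot tell whether the KO libraries were deeper. It stays open whether the transcripts of Gzmb, Gzmc, Nkg7, Il1b and Ccl22 came from such cells or from the Th17 cells, and a genotype effect on the T cells was not tested apart from it.

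KO replicate 3 lay nearer to the WT libraries than to the other KO libraries. The SD of log2 differences was 0.342 from KO replicates 1 and 2 and 0.236 from WT, against 0.189 between WT libraries. A mislabelled sample is argued against by Sirt2, at 10.9 FPKM in KO replicate 3 and 19.9 FPKM in the lowest WT library. Gene length was related to the differences from WT, with Spearman correlations across genes of -0.33, -0.46 and 0.23 in KO replicates 1 to 3, but removing length and GC trends left the ratio of its distance from the other KO libraries to the distance between WT libraries at 1.71, from 1.81, and without KO replicate 3 still 895 genes were called. Length and GC trends were therefore not the whole source of the pattern, and no biological explanation was tested.

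Within 5 Mb of Sirt2, a distance set after the values were seen, 18 of 135 tested genes (13.3 percent) had an unadjusted p under 0.05, 7 higher and 11 lower in KO, against 5.50 percent elsewhere (Fisher's exact p = 5.19e-04, two-sided). By distance the share was 16.7 percent up to 1 Mb, 16.0 percent from 1 to 2 Mb and 6.98 percent from 2 to 5 Mb, while groups did not overlap for 21 of the 135 (15.6 percent) against 11.1 percent elsewhere (Fisher's exact p = 0.128, two-sided), where chance gives 10 percent. The share of 7911 overlapping windows of as many neighbouring genes elsewhere that held as many was 1.26e-04, a count that restates the pattern and leaves open a difference in the DNA around Sirt2 between genotypes, a local effect of Sirt2 loss or of the editing itself. Length and GC bias is argued against as the whole source, since 11.2 percent remained under 0.05 after its removal, against 6.60 percent elsewhere. With a library left out, the shares in the window and elsewhere were 5.97 and 3.17 percent without KO replicate 1, 5.26 and 4.50 percent without KO replicate 2, and 38.6 and 32.4 percent without KO replicate 3, and 8.33 and 2.73 percent without WT replicate 1, 7.52 and 3.42 percent without WT replicate 2, and 9.70 and 3.37 percent without WT replicate 3.

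The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. For genes, 1 of the 10 splits gave as many as 12, the real one, and the highest other gave 2. For transcripts, 5 of the 10 gave as many as 8, and the highest other gave 11. For lists, 2 of the 10 gave as many as 10, and the highest other gave 11. The split of KO replicates 1 and 2 with WT replicate 3 against the rest gave 2186 genes at an unadjusted p under 0.05, against 610 for the real split, which points to a structure of the samples other than genotype. Transcripts under 0.1 FPKM in all libraries of one side and at 1 FPKM or more in all of the other numbered 25 in the real split and 12 to 25 in the others.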
